A study of Homo sapiens with 24 samples.

How the data were processed

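RNA of OV2008 and MCAS, both human ovarian cancer cell lines by their labels (identity was not checked here), was measured on 1-colour Illumina bead arrays with 47323 probes. Per the labels' protocols, cells were grown as 3D structures for 4 days in polyHEMA-coated wells, with 2% serum and 2% Matrigel, a basement membrane extract. They were then given 1 uM NVP-BEZ235 (BEZ235), a dual inhibitor of PI3K and mTOR, or DMSO, its solvent, for 6 h or 24 h. Per the same protocols, 6 wells were pooled for each sample and the RNA was isolated with TRIzol and labelled with biotin. The labels put the 24 arrays in 8 groups of 3, one for each cell line, treatment and time. Nothing says whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

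Per the file headers, the deposited table of unnormalized values holds, for each probe and array, an average bead signal as an intensity on a linear scale. Per the same file headers, the authors' software computed and deposited beside each signal a detection p-value, whose steps fit a rank among 770 negative control bead types. Per the submitters' processing notes the arrays were read with GenomeStudio, whose version is not given in the sources used here. The columns of that table carry a letter (A, B or C) within each group, which no label ties to a numbered sample, so each column was assigned to its group only and its letter pairs nothing. A second deposited table, the authors' value table, gives 1 intensity per probe and numbered sample, again on a linear scale. Its scale and centring were worked out from the values: sorted values matched within 1.03 units among the 12 OV2008 columns and within 1.35 among the 12 MCAS columns, with a different distribution for each line, and the lowest value was -33.8. This pattern is that of background subtraction followed by quantile normalization within each cell line, and the exact settings stay unknown. Its direction was settled, since each of the 24 columns ranked the probes like a signal column of its own group (lowest rank correlation 0.999998). Its column medians lay between 11.2351 and 11.2705 in OV2008 and between 11.3799 and 11.4205 in MCAS. That table served only as an alternative, and the baseline levels of the cell lines were not compared with each other in it.

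From the unnormalized intensities, the background was corrected by neqc of limma 3.58.1 in R 4.3.3 (normexp fitted from the detection p-values, offset 16, quantile normalization over all 24 arrays, log2). Probes with a detection p-value under 0.01 on all 3 arrays of at least 1 group were kept, 18270 in number. Gene names came from the platform annotation: 30113 probes had 1 gene symbol, 8 had several and 17202 had none here. Symbols were checked through the Entrez identifier, which the reference held for 30074 named probes, and none needed an update. The 3631 kept probes without 1 symbol stayed out of the gene tests. For the 2886 genes with more than 1 kept probe, the probe of highest mean over all arrays was used, which left 11067 genes. Among called genes with several probes, another probe was called in the opposite direction for 5 of 895 genes in OV2008 at 6 h, 10 of 1012 in OV2008 at 24 h, 39 of 1408 in MCAS at 6 h and 33 of 1453 in MCAS at 24 h. No genome build was named and no coordinates are given.

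One linear model with a mean per group was fitted over all 24 arrays (lmFit and eBayes, 16 residual degrees of freedom, 6.85 prior degrees of freedom). From it came 11 two-sided contrasts: 4 effects of BEZ235 against DMSO, 4 differences between those effects, the baseline difference between the lines under DMSO, and 24 h against 6 h under DMSO in each line. P-values were adjusted by the Benjamini-Hochberg method over the genes of each contrast, and a gene was called at an adjusted p-value under 0.05. All changes are log2 values with the standard error (SE) of limma, 3 arrays per group, and folds are on the scale with offset 16, which understates the change of dim genes.

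Before the data were examined, 33 gene lists, a panel of 30 genes, the design, the alternatives and the rule for named genes were fixed. The lists covered receptor and adaptor genes linked to PI3K feedback, FOXO targets and PI3K-AKT-mTOR components, metabolism (cholesterol, fatty acid, glycolysis and hypoxia, amino acid and ATF4, aminoacyl-tRNA synthetase, oxidative phosphorylation), DNA replication, mitosis and G1 regulators, ribosome biogenesis and ribosomal proteins, and lysosome and autophagy. They also covered BCL2 families, p53, interferon, antigen presentation, inflammatory, ERK, integrin, endoplasmic reticulum stress, heat shock and NRF2 genes, and squamous, mucinous, ovarian, mesenchymal, fibroblast, leukocyte and endothelial markers. The 30 lists with at least 5 tested genes were compared with all other genes by camera at a preset correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move one way on balance, and does not compare them with other genes. For each list, calls were also counted after adjustment over the list alone.

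Named genes were, for each effect, the 8 of largest rise and the 8 of largest fall among called genes whose treated and control arrays did not overlap and which were detected on at least 1 array of both groups. Chance gives no overlap between 3 and 3 arrays for 10% of genes. Up to 3 members per list by the same conditions, the panel in every effect, and the 5 largest in each direction of every other contrast were added. INSR, PIK3CA and RICTOR of the panel were not analysed here, and some other panel genes are not reported here. Genes of near-identical families, such as HSPA1A and HSPA1B, the AKR1B and AKR1C genes, the PSG genes and the metallothioneins, are uncertain as single genes, because a probe may bind several copies.

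Alternatives were no background correction, offset 50, median scaling in place of quantile, the authors' value table, no detection filter, detection on all 24 arrays, the mean of a gene's probes, each kept probe alone, only the arrays compared, eBayes with trend and robust options, array weights, and each array left out in turn. A replicate block on the authors' value table, and median scaling over the 11847 probes detected on all arrays, were added after seeing the data. Only the gene and list tests were run on simulated data, with 200 of 11067 genes changed. In the 4 effects, 94.6% to 98.7% of genes with a simulated log2 change of 1 were called, against 41.7% to 65.1% of those with 0.5, and 3.98% to 5.85% of all calls were of unchanged genes. With no list changed, 0 of 30 lists passed. The simulated genes varied independently, so this cannot show how often correlated lists pass at the preset correlation. The glycolysis and hypoxia list had an estimated correlation of 0.267. The number of arrays limits the precision. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.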

Results

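The arrays measured RNA of OV2008 and MCAS cells grown as 3D structures, with 3 arrays for each of the 8 combinations of cell line, treatment and time. The comparisons ask which transcripts change when PI3K and mTOR are inhibited, how far the 2 cell lines share the change, and how it differs between 6 h and 24 h. The median signal of an array lay between 73.01 and 83.2, and 32.3% to 36.1% of the probes were detected. Across genes, an array correlated with the others of its group at a mean r of 0.988 to 0.996. The first principal component, which separated the cell lines, held 81.9% of the variance and the second 6.89%. The median SD between arrays of a group ranged from 0.0939 log2 units in OV2008 treated for 24 h to 0.162 in MCAS treated for 6 h. All changes below are relative to the other genes: under median scaling the median change of all genes was -0.13 in OV2008 at 6 h, -0.11 in OV2008 at 24 h and -0.20 in MCAS at 6 h, and under median scaling over detected probes it was 0.11 in MCAS at 6 h. Values per array of genes that recur in the comparisons are shown in the plot of 8 genes.

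**Figure D1:**
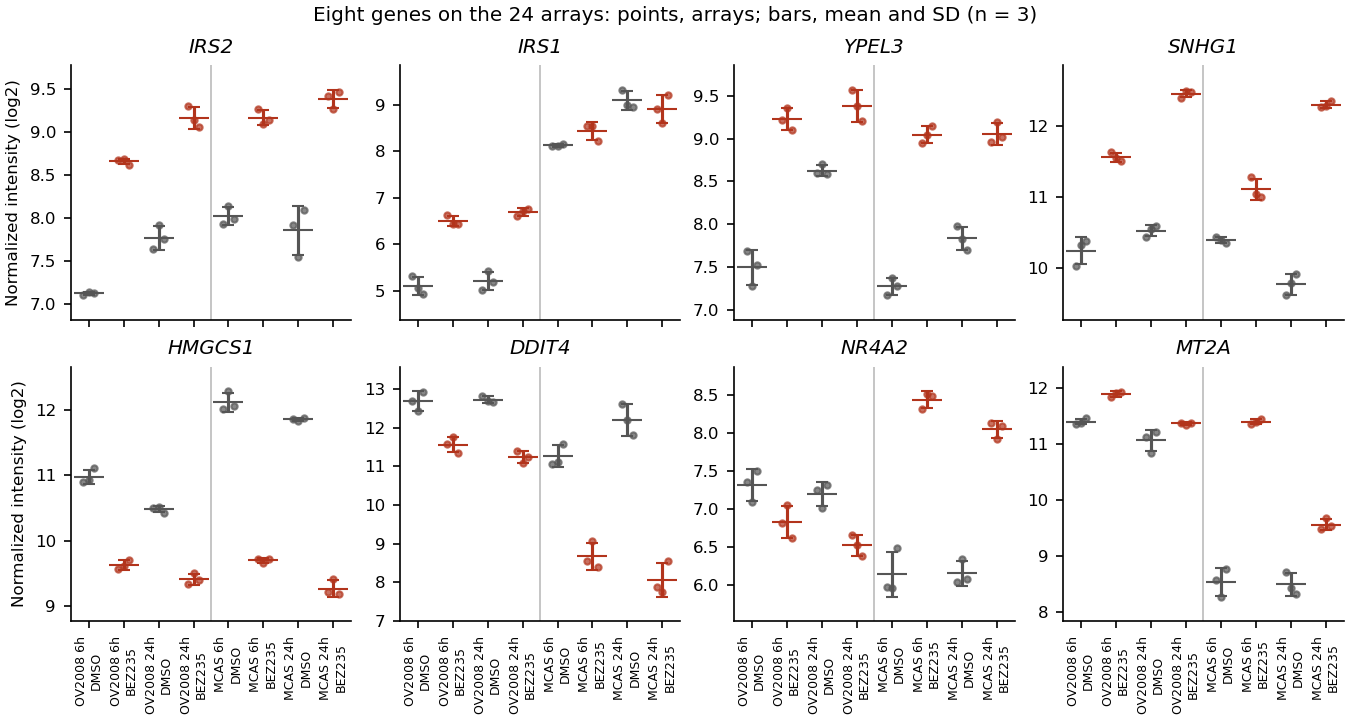
Normalized intensity (log2) of 8 genes on the 24 arrays, by cell line, time and treatment; points are arrays and bars the mean and SD of 3 arrays. IRS2 was higher with BEZ235 in all 4 comparisons (log2 changes 1.54, 1.40, 1.15 and 1.53 in OV2008 at 6 h, OV2008 at 24 h, MCAS at 6 h and MCAS at 24 h), while MT2A differed by 2.37 between the effects of the cell lines at 6 h.

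In OV2008 after 6 h of BEZ235, genes of growth factor receptors and their adaptors and targets of FOXO transcription factors rose, while genes of cholesterol and fatty acid synthesis and heat shock genes fell. The largest rises were those of GRB7, an adaptor protein of receptor tyrosine kinases (log2 change 1.76, SE 0.132, adjusted p = 1.84e-09, n = 3 arrays per group), YPEL3 (1.73, SE 0.114) and SNHG7, a host gene of small nucleolar RNAs (1.72, SE 0.105). RGCC, a regulator of the cell cycle (1.71), ST6GALNAC1, a sialyltransferase (1.71), ABTB1 (1.60), PPP3CA-DT (1.59) and CLDN23, a claudin (1.58), followed. The largest falls were those of the non-coding RNA VTRNA2-1 (-1.90, SE 0.135, adjusted p = 1.26e-09), EDN2, an endothelin (-1.84), IGFBP5, which binds insulin-like growth factors (-1.75), KDELR3 (-1.75), TIGAR, a regulator of glycolysis (-1.69), the sugar transporter SLC2A6 (-1.59), PFKFB4, a kinase that controls glycolysis (-1.56), and GBP6, a guanylate-binding protein (-1.55). Each of these 16 genes had an adjusted p of at most 4.30e-05. CLDN23 was detected on only 1 of the 3 DMSO arrays, and on the treated arrays VTRNA2-1 and SLC2A6 were detected on 1 and IGFBP5, KDELR3 and PFKFB4 on 2.

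The list of receptor and adaptor genes linked to PI3K feedback held 19 genes, of which 8 were tested. Of these 8 genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.84, camera adjusted p = 8.31e-06). They included IRS2, an adaptor of insulin receptors (1.54, SE 0.113), MET (0.88), EGFR (0.79) and ERBB3 (0.69). IRS1 and IGF1R were detected on no DMSO array and were at least 2.14-fold and at least 1.45-fold higher. FOXO targets rose in 22 of 35 genes and fell in none (22 adjusted over the list alone, median 0.45, adjusted p = 1.34e-11). Among them were PIK3IP1, an inhibitor of PI3K (1.57), and FBXO32, a ubiquitin ligase (1.53). Of 20 cholesterol synthesis genes, 15 fell and none rose (15 and 1 adjusted over the list alone, median -0.50, adjusted p = 6.82e-08), with HMGCS1, an early enzyme of the pathway, at -1.35 (SE 0.089). Fatty acid synthesis genes fell in 11 of 16 and rose in 1 (12 and 2 adjusted over the list alone, median -0.40, adjusted p = 1.92e-05). The largest falls were those of FASN (-1.54) and ACLY (-0.98). Heat shock genes fell in 15 of 22 (15 fell and 1 rose adjusted over the list alone, median -0.65, adjusted p = 4.31e-08). These included HSPA1A (-1.29), HSPA1B (-1.12) and HSPH1 (-1.02). These 5 lists also passed with an estimated correlation.

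Another 9 lists passed only with the preset correlation. Glycolysis and hypoxia genes fell in 14 of 37 (14 adjusted over the list alone, median -0.26, adjusted p = 5.13e-05, and adjusted p = 0.250 with an estimated correlation), with the hexokinase HK2 at -1.18. Aminoacyl-tRNA synthetases, which charge tRNAs, fell in 7 of 16 (8 adjusted over the list alone, median -0.22, adjusted p = 0.00114, and adjusted p = 0.126 with an estimated correlation). Ribosome biogenesis genes fell in 18 of 57 and rose in 2 (20 and 3 adjusted over the list alone, median -0.21, adjusted p = 0.000673, and adjusted p = 0.228 with an estimated correlation). Oxidative phosphorylation genes fell in 9 of 48 (8 adjusted over the list alone, median -0.19, adjusted p = 0.00070, and adjusted p = 0.123 with an estimated correlation). Endoplasmic reticulum stress genes fell in 11 of 25 and rose in 3 (11 and 4 adjusted over the list alone, median -0.22, adjusted p = 0.00455, and adjusted p = 0.102 with an estimated correlation). DDIT3 (1.48) and PPP1R15A (1.58), which act in the stress response to unfolded proteins, were among those that rose. Lysosome and autophagy genes rose in 21 of 65 and fell in 3 (21 and 3 adjusted over the list alone, median 0.13, but -0.06 under median scaling, adjusted p = 0.00423, and adjusted p = 0.0808 with an estimated correlation). Among them were the autophagy adaptor SQSTM1 (1.02) and GABARAPL1 (1.17). ERK output genes rose in 13 of 29 and fell in 1 (13 and 2 adjusted over the list alone, median 0.10, adjusted p = 0.00147, and adjusted p = 0.102 with an estimated correlation), with the feedback phosphatase DUSP6 at 1.07 and SPRED2 at 0.94. Integrin and laminin genes, which mediate attachment to the matrix, rose in 6 of 24 (6 adjusted over the list alone, median 0.07, but -0.06 under median scaling, adjusted p = 0.0295, and adjusted p = 0.123 with an estimated correlation). Among them were ITGA2 (1.31) and LAMB3 (1.20). Squamous markers fell in 11 of 32 and rose in 2 (12 and 2 adjusted over the list alone, median -0.14, adjusted p = 0.0381, and adjusted p = 0.164 with an estimated correlation). The integrin call ended when only the arrays compared were fitted (adjusted p = 0.0667), without OV2008 DMSO 6 h replicate A (0.0521) and without OV2008 BEZ235 6 h replicate C (0.0519). The squamous call ended without background correction (adjusted p = 0.0585), with genes detected on all arrays (0.261), with only the arrays compared (0.0718), without OV2008 DMSO 6 h replicate C (0.0881) and without OV2008 BEZ235 6 h replicate B (0.0988).

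The lists for DNA replication (3 of 49 higher and 10 lower, 3 and 10 adjusted over the list alone, median -0.06) and mitosis (5 of 61 higher and 3 lower, 5 and 3 adjusted over the list alone, median 0.06) did not pass, both with an adjusted p = 0.318, though CDT1 rose by 1.47 and CCNE1, a cyclin of the entry into S phase, fell by 0.84. In all, 3156 of 11067 genes (28.5%) passed in OV2008 at 6 h, 1578 higher and 1578 lower, and 158 of them changed at least 2-fold (98 higher, 60 lower). The share of called genes that were higher was 50% and became 22.6% under median scaling and 53.6% under median scaling over detected probes.

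**Figure D2:**
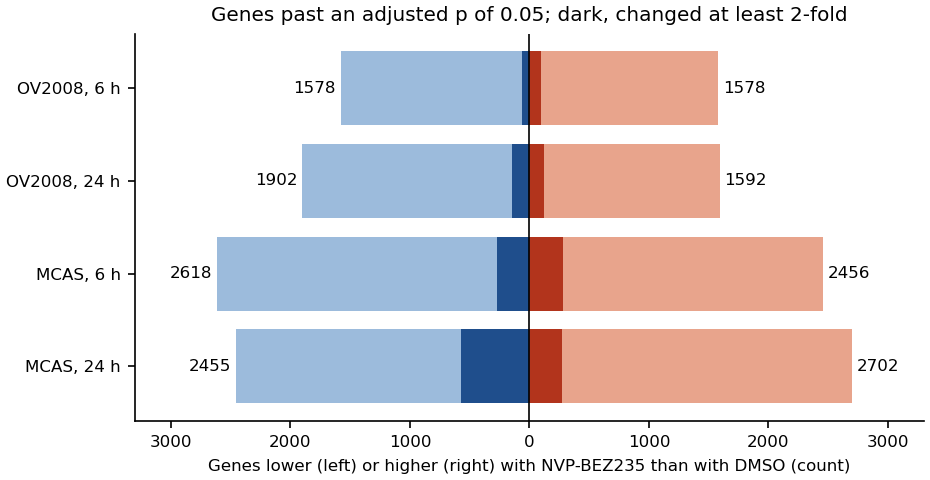
Number of genes higher (right) and lower (left) with BEZ235 than with DMSO at an adjusted p under 0.05, for each cell line and time; dark parts are genes changed at least 2-fold. Called genes numbered 3156 and 3494 in OV2008 and 5074 and 5157 in MCAS at 6 h and 24 h, and the share higher in OV2008 at 6 h, OV2008 at 24 h and MCAS at 6 h dropped under median scaling to 22.6%, 28.03% and 19.5% but was 53.6%, 50.9% and 61.3% under median scaling over detected probes.

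After 24 h in OV2008, genes of mitosis, DNA replication, glycolysis and hypoxia, and lipid synthesis fell, and receptor and adaptor genes rose. PSG5 and PSG3, pregnancy-specific glycoproteins, had the largest rises (2.85, SE 0.165, adjusted p = 1.32e-11, 7.19-fold, and 2.28), each detected on only 1 of the 3 DMSO arrays. SNHG1, another host of small nucleolar RNAs (1.93), PLAC8 (1.91), the actin-binding TAGLN (1.89), RGCC (1.89), the matrix protein TGFBI (1.83) and the transcription factor ATOH8 (1.82) came next. COXFA4L2, a hypoxia-induced mitochondrial protein, fell the most (-4.37, SE 0.149, adjusted p = 1.31e-15, 20.6-fold), followed by GBP6 (-3.03), IGFBP5 (-3.02), the chemokine CXCL14 (-2.55), the collagen cross-linking enzyme LOX (-2.50), myoglobin MB (-2.18) and the aldo-keto reductases AKR1B15 (-2.16) and AKR1B10 (-2.15). All 16 had an adjusted p of at most 1.76e-05, and on the treated arrays COXFA4L2 was detected on 2 and MB on 1.

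Mitosis genes fell in 52 of 61 and rose in none (55 adjusted over the list alone, median -0.61, adjusted p = 7.24e-19). Among them were CDC20 (-1.13), BUB1 (-0.98) and BIRC5 (-0.94). DNA replication genes fell in 32 of 49 and rose in 3 (33 and 3 adjusted over the list alone, median -0.39, adjusted p = 3.71e-08), with the ribonucleotide reductase subunit RRM2 at -1.15, while CDT1, which licenses replication origins, rose by 1.10. Glycolysis and hypoxia genes fell in 28 of 37 and rose in 1 (31 and 1 adjusted over the list alone, median -0.71, adjusted p = 1.71e-13). The largest falls were those of PFKFB4 (-1.98, detected on 2 of the 3 treated arrays), ALDOC (-1.78) and BNIP3 (-1.77). Cholesterol synthesis genes fell in 14 of 20 (15 adjusted over the list alone, median -0.51, adjusted p = 1.21e-07). INSIG1 was at -1.58 and DHCR7 at -1.52. Fatty acid synthesis genes fell in 11 of 16 (11 adjusted over the list alone, median -0.66, adjusted p = 1.49e-08), with the desaturase SCD at -1.62. Receptor and adaptor genes rose in 6 of 8 and fell in 1 (6 and 1 adjusted over the list alone, median 0.72, adjusted p = 0.000163). These included IRS2 (1.40), MET (1.13) and IRS1 (1.48, detected on 1 of the 3 DMSO arrays). IGF1R, detected on no DMSO array, was at least 1.24-fold higher. Ribosomal protein genes rose in 13 of 78 and fell in 1 (13 and 1 adjusted over the list alone, median 0.11, adjusted p = 0.00084). RPL14 was at 1.01 and RPL37 at 0.85. Heat shock genes fell in 15 of 22 and rose in 2 (15 and 2 adjusted over the list alone, median -0.47, adjusted p = 0.000375). NRF2 targets fell in 11 of 21 and rose in 2 (12 and 3 adjusted over the list alone, median -0.23, adjusted p = 0.000743). AKR1C2 was at -1.57 and ABCC3 at 1.53. Squamous markers fell in 18 of 32 and rose in 4 (19 and 4 adjusted over the list alone, median -0.42, adjusted p = 4.07e-06). Among them were S100A8 (-1.43), the connexin GJB6 (-1.37) and the keratin KRT14 (-1.28). These 10 lists also passed with an estimated correlation.

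A further 5 lists passed only with the preset correlation. FOXO targets rose in 16 of 35 and fell in 2 (17 and 2 adjusted over the list alone, median 0.27, adjusted p = 0.00094, and adjusted p = 0.0904 with an estimated correlation). CREBRF was at 1.06. Ribosome biogenesis genes rose in 15 of 57 and fell in 2 (14 and 2 adjusted over the list alone, median 0.14, adjusted p = 0.00741, and adjusted p = 0.338 with an estimated correlation). In the DMSO cultures of OV2008 these genes fell between 6 h and 24 h. Oxidative phosphorylation genes fell in 16 of 48 and rose in 1 (16 and 1 adjusted over the list alone, median -0.24, adjusted p = 0.00072, and adjusted p = 0.0904 with an estimated correlation). ERK output genes rose in 10 of 29 and fell in 1 (10 and 2 adjusted over the list alone, median 0.13, adjusted p = 0.00307, and adjusted p = 0.0904 with an estimated correlation). DUSP5 was at 1.35 and SPRED1 at 1.06. Interferon-stimulated genes fell in 16 of 45 and rose in 4 (16 and 4 adjusted over the list alone, median -0.17, adjusted p = 0.0256, and adjusted p = 0.161 with an estimated correlation), a call that ended with genes detected on all arrays (adjusted p = 0.0626) and without OV2008 BEZ235 24 h replicate A (0.0613). The squamous call ended with genes detected on all arrays too (adjusted p = 0.0626). In total 3494 genes (31.6%) passed, 1592 higher and 1902 lower, and 266 changed at least 2-fold (119 higher, 147 lower). The share higher was 45.6%, against 28.03% under median scaling and 50.9% under median scaling over detected probes.

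In MCAS after 6 h, DNA replication and cholesterol synthesis genes fell, and ERK output, integrin, FOXO target and lysosomal genes rose. The metallothionein MT2A rose the most (2.86, SE 0.115, adjusted p = 1.59e-14, 7.28-fold), ahead of the serpin SERPIND1 (2.65), FAM43A (2.60), the kinase PIM1 (2.56), the stress-induced cytokine GDF15 (2.55), the metallothionein MT1E (2.46), the complement regulator CD55 (2.35) and the nuclear receptor NR4A2 (2.29). PSAT1, an enzyme of serine synthesis, fell the most (-2.71, SE 0.12, adjusted p = 9.18e-14), followed by DDIT4, an inhibitor of mTOR signalling (-2.58), the glutamate transporter SLC1A3 (-2.44), HMGCS1 (-2.42, SE 0.089), SQLE (-2.18), PFKFB4 (-2.18), PRR15L (-2.14) and INSIG1 (-2.06). Each of the 16 had an adjusted p of at most 1.83e-07. PIM1 was detected on 1 of the 3 DMSO arrays, and SLC1A3 on 1 and PRR15L on 2 of the treated arrays.

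DNA replication genes fell in 44 of 49 and rose in none (45 adjusted over the list alone, median -0.98, adjusted p = 1.36e-22). Among them were CDC25A (-1.92), MCM10 (-1.92) and UHRF1 (-1.89). Cholesterol synthesis genes fell in 15 of 20 and rose in 1 (15 and 1 adjusted over the list alone, median -0.95, adjusted p = 9.63e-10), and fatty acid synthesis genes fell in 13 of 16 (13 adjusted over the list alone, median -0.49, adjusted p = 1.57e-05). ACLY was at -1.15. ERK output and immediate early genes rose in 25 of 29 and fell in 1 (25 and 1 adjusted over the list alone, median 1.03, adjusted p = 1.88e-14). These included the transcription factor EGR1 (2.11) and the receptor EPHA4 (1.85). Integrin and laminin genes rose in 14 of 24 (14 adjusted over the list alone, median 0.37, adjusted p = 8.05e-05). ITGA2 was at 1.54, ITGB5 at 1.37 and ITGB4 at 1.26. FOXO targets rose in 24 of 35 and fell in 5 (24 and 5 adjusted over the list alone, median 0.64, adjusted p = 3.64e-07). FBXO32 was at 2.28 and YPEL3 at 1.77. Receptor and adaptor genes rose in 5 of 8 and fell in 1 (6 and 1 adjusted over the list alone, median 0.75, adjusted p = 0.00231). MET was at 1.17, IRS2 at 1.15 and EGFR at 0.83. Lysosome and autophagy genes rose in 34 of 65 and fell in 7 (34 and 8 adjusted over the list alone, median 0.26, adjusted p = 0.00054). Among them were the cholesterol exporter NPC1 (1.75), the autophagy kinase ULK1 (1.09) and MAP1LC3B (1.06). Inflammatory cytokine and NF-kB target genes rose in 10 of 26 and fell in 4 (10 and 4 adjusted over the list alone, median 0.25, adjusted p = 0.0250). LIF was at 1.63 and PTGS2 at 1.51, and the call ended with genes detected on all arrays (adjusted p = 0.0576). Heat shock genes fell in 14 of 22 (14 adjusted over the list alone, median -0.47, adjusted p = 8.05e-05). HSPA1A was at -1.55, HSPA1B at -1.53 and DNAJA1 at -1.35. Oxidative phosphorylation genes fell in 26 of 48 and rose in 1 (26 and 2 adjusted over the list alone, median -0.27, adjusted p = 4.26e-05). CYCS was at -1.41 and UQCRB at -1.39. These 11 lists also passed with an estimated correlation.

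The remaining 3 called lists passed only with the preset correlation. Mitosis genes fell in 30 of 61 and rose in 3 (31 and 4 adjusted over the list alone, median -0.28, adjusted p = 0.00040, and adjusted p = 0.216 with an estimated correlation), with the checkpoint gene MAD2L1 at -1.19. Ribosome biogenesis genes fell in 24 of 57 and rose in 2 (24 and 2 adjusted over the list alone, median -0.20, adjusted p = 0.00523, and adjusted p = 0.339 with an estimated correlation). Of 37 glycolysis and hypoxia genes, 17 fell and 7 rose (18 and 7 adjusted over the list alone, median -0.38, adjusted p = 0.0133, and adjusted p = 0.482 with an estimated correlation). PGAM1 was at -1.24 and NDRG1 at 1.36. The genes called numbered 5074 (45.8%), 2456 higher and 2618 lower, and 553 changed at least 2-fold (285 higher, 268 lower). The share higher was 48.4%, against 19.5% under median scaling and 61.3% under median scaling over detected probes.

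After 24 h in MCAS, nearly all mitosis, DNA replication and cholesterol synthesis genes were lower than with DMSO. The largest rises were those of the collagenase MMP1 (2.98, SE 0.19, adjusted p = 6.29e-12) and PAEP, a secreted glycoprotein of the endometrium (2.77, SE 0.089, adjusted p = 6.52e-17). ARSG (2.54), SNHG1 (2.53), the receptor kinase AXL (2.45), PLA2G4C (2.44), PHACTR3 (2.39) and the cholesterol exporter ABCA1 (2.24) followed. The largest falls were those of ANGPTL4, a hypoxia-induced inhibitor of lipoprotein lipase (-4.15, SE 0.274, adjusted p = 1.25e-11, 17.7-fold), DDIT4 (-4.14), INSIG1 (-3.72, SE 0.099), FGFBP1 (-3.63), RARRES1 (-3.61), the desaturase FADS1 (-3.55), DMBT1 (-3.47) and ACAT2 (-3.40). For all 16 genes the adjusted p was at most 1.25e-11. ARSG was detected on 2 of the 3 DMSO arrays, and ANGPTL4, FADS1 and DMBT1 on 1 of the 3 treated arrays.

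Mitosis genes fell in 60 of 61 (60 adjusted over the list alone, median -1.71, adjusted p = 8.75e-43). These included CENPM (-2.62), CDK1 (-2.31) and ANLN (-2.21). DNA replication genes fell in 46 of 49 (46 adjusted over the list alone, median -1.60, adjusted p = 3.41e-34). TK1 was at -3.14, CDC45 at -2.94 and TYMS at -2.91. Cholesterol synthesis genes fell in 19 of 20 and rose in none (19 and 1 adjusted over the list alone, median -1.65, adjusted p = 1.71e-18). DHCR7 was at -3.07. Fatty acid synthesis genes fell in 12 of 16 and rose in 1 (12 and 1 adjusted over the list alone, median -0.995, adjusted p = 1.01e-08). SCD was at -2.46 and FASN at -2.24. Of 37 glycolysis and hypoxia genes, 31 fell and 1 rose (31 and 1 adjusted over the list alone, median -1.01, adjusted p = 4.52e-13). ALDOC was at -3.18, PFKFB4 at -2.57 and EGLN3 at -2.03 (detected on 1 of the 3 treated arrays). Endoplasmic reticulum stress genes fell in 18 of 25 and rose in 2 (20 and 2 adjusted over the list alone, median -0.53, adjusted p = 4.76e-06). Among them were SDF2L1 (-1.80) and MANF (-1.45), while DDIT3 rose by 1.34. NRF2 targets fell in 14 of 21 (14 fell and 1 rose adjusted over the list alone, median -0.51, adjusted p = 1.40e-05). AKR1C2 was at -2.49 and NQO1 at -1.30. Mucinous and glandular markers fell in 15 of 29 and rose in 2 (16 and 2 adjusted over the list alone, median -0.29, adjusted p = 6.40e-05). TFF3 was at -2.20, CEACAM5 at -2.05 and GPX2 at -1.98. Inflammatory genes fell in 14 of 26 and rose in 4 (15 and 4 adjusted over the list alone, median -0.34, adjusted p = 0.00661). CXCL6 was at -3.22, SAA2 at -1.97 and SAA1 at -1.79. Ribosomal protein genes rose in 30 of 78 and fell in 2 (28 and 2 adjusted over the list alone, median 0.16, adjusted p = 0.00297). RPL37 was at 1.24 and RPL14 at 1.16. These 10 lists also passed with an estimated correlation.

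Another 6 lists in MCAS at 24 h passed only with the preset correlation. FOXO targets rose in 18 of 35 and fell in 9 (20 and 9 adjusted over the list alone, median 0.28, adjusted p = 0.00163, and adjusted p = 0.102 with an estimated correlation). TXNIP was at 1.53 and DEPP1 at -1.55. Amino acid and ATF4 targets fell in 17 of 30 and rose in 5 (17 and 6 adjusted over the list alone, median -0.41, adjusted p = 0.00297, and adjusted p = 0.0517 with an estimated correlation), with PHGDH, an enzyme of serine synthesis, at -2.81 and the amino acid transporter SLC7A5 at -1.83. Oxidative phosphorylation genes fell in 21 of 48 and rose in 2 (22 and 2 adjusted over the list alone, median -0.23, adjusted p = 0.00163, and adjusted p = 0.109 with an estimated correlation). Lysosome and autophagy genes rose in 30 of 65 and fell in 8 (30 and 8 adjusted over the list alone, median 0.24, adjusted p = 0.00949, and adjusted p = 0.0725 with an estimated correlation). Interferon-stimulated genes fell in 20 of 45 and rose in 6 (22 and 7 adjusted over the list alone, median -0.26, adjusted p = 0.00377, and adjusted p = 0.0855 with an estimated correlation). IFITM1 was at -2.02 and IFI27 at -1.68. ERK output genes rose in 13 of 29 and fell in 2 (13 and 2 adjusted over the list alone, median 0.19, adjusted p = 0.0131, and adjusted p = 0.146 with an estimated correlation). Receptor and adaptor genes did not pass (5 of 8 higher and 1 lower, 5 and 1 adjusted over the list alone, median 0.46, adjusted p = 0.235), though IRS2 rose by 1.53. Heat shock genes did not pass either (2 of 22 higher and 5 lower, 2 and 4 adjusted over the list alone, median -0.10, adjusted p = 0.397). With genes detected on all arrays the lysosomal, inflammatory and ERK calls ended (adjusted p = 0.0706, 0.118 and 0.0706). In total 5157 genes (46.6%) passed, 2702 higher and 2455 lower, and 848 changed at least 2-fold (275 higher, 573 lower).

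**Figure D3:**
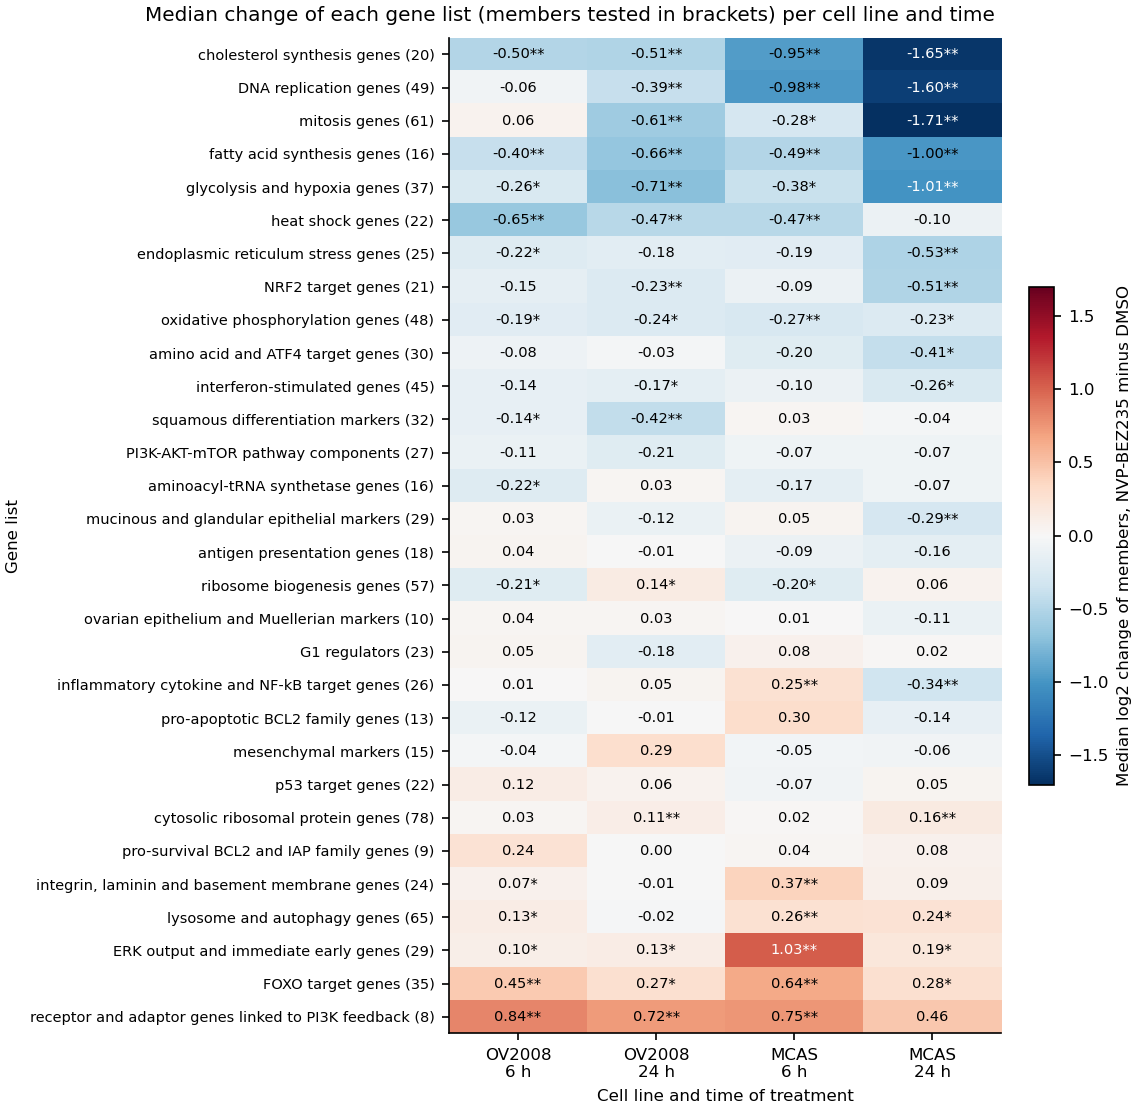
Median log2 change of the members of 30 gene lists (with the number of tested members) in 4 comparisons; 1 asterisk marks an adjusted p under 0.05 with the preset correlation and a pair of asterisks also with an estimated one. Mitosis genes had medians of 0.06, -0.61, -0.28 and -1.71 in OV2008 at 6 h, OV2008 at 24 h, MCAS at 6 h and MCAS at 24 h, and under median scaling the medians of 0.13 and 0.07 of the lysosome and integrin lists in OV2008 at 6 h became -0.06 and -0.06.

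Lists for 8 other groups passed in none of the 4 comparisons (counts are in the order OV2008 at 6 h, OV2008 at 24 h, MCAS at 6 h and MCAS at 24 h). Of 27 PI3K-AKT-mTOR pathway components, 3, 3, 7 and 3 were higher and 8, 7, 7 and 8 lower (the same counts adjusted over the list alone), with a lowest adjusted p of 0.0513 in OV2008 at 24 h. Of 23 G1 regulators, 4, 3, 7 and 7 were higher and 5, 10, 6 and 9 lower (4, 3, 8 and 9, and 5, 10, 6 and 10, adjusted over the list alone), and the cell cycle inhibitor CDKN1A fell by 2.55 in MCAS at 24 h. Of 9 pro-survival BCL2 and IAP genes, 3, 2, 2 and 3 were higher and 0, 1, 0 and 2 lower (3, 2, 1 and 3, and 0, 1, 0 and 2, adjusted over the list alone). Of 13 pro-apoptotic BCL2 genes, 2, 3, 5 and 4 were higher and 2, 2, 1 and 3 lower (2, 3, 5 and 4, and 2, 2, 1 and 4, adjusted over the list alone), and PMAIP1 rose by 1.11 and 1.08 in MCAS at 6 h and 24 h. Of 22 p53 targets, 4, 3, 4 and 5 were higher and 4, 4, 7 and 8 lower (4, 3, 5 and 6, and 4, 5, 7 and 8, adjusted over the list alone). Of 18 antigen presentation genes, 2, 4, 3 and 4 were higher and 2, 2, 4 and 5 lower (2, 4, 3 and 4, and 2, 2, 4 and 7, adjusted over the list alone). Of 10 ovarian markers, 2, 1, 1 and 2 were higher and 2, 2, 2 and 4 lower (2, 1, 1 and 2, and 2, 2, 2 and 5, adjusted over the list alone), with WFDC2, a marker of ovarian tumours, at -2.42 in MCAS at 24 h. Of 15 mesenchymal markers, 5, 7, 2 and 2 were higher and 1, 3, 3 and 4 lower (6, 7, 2 and 2, and 1, 4, 3 and 4, adjusted over the list alone). Fibroblast, leukocyte and endothelial markers were too few among the tested genes for a list test. Of the 3 fibroblast genes, COL1A1 fell in OV2008 at 24 h (-0.39, adjusted p = 0.0296) and MFAP5, detected on no DMSO array of MCAS, was at least 1.29-fold higher there at 6 h (adjusted p = 0.00116) and was detected on 2 of the 3 treated arrays at 24 h (adjusted p = 0.00759). Of the 4 leukocyte genes, CD14 was detected on 2 of the 3 DMSO arrays and no treated array of OV2008 at 24 h and was at least 1.18-fold lower (adjusted p = 0.00223). CD14 fell in MCAS at 6 h and 24 h (-1.0 and -1.65), LYZ fell in MCAS at 24 h (-0.50) and CD68 rose in MCAS at 6 h (0.51, adjusted p = 0.0130). The endothelial gene VWF was detected on no treated array of OV2008 at 24 h and was at least 2.58-fold lower (adjusted p = 2.25e-08). Lists whose median, mean and test differed in sign were G1, pro-apoptotic, p53 and mesenchymal genes in OV2008 at 6 h, the ATF4, aminoacyl-tRNA synthetase, lysosome, pro-survival, pro-apoptotic, p53, antigen presentation, integrin and ovarian lists in OV2008 at 24 h, ribosomal protein, p53 and ovarian genes in MCAS at 6 h, and G1, pro-survival, pro-apoptotic and p53 genes in MCAS at 24 h; none of these passed.

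The effect of BEZ235 differed between the cell lines at both times. At 6 h the effect in MCAS was above that in OV2008 for NR4A2 (difference 2.78, SE 0.200, adjusted p = 1.63e-09), FAM43A (2.48), MT2A (2.37), MT1E (2.37) and TMEM158 (2.32), and below it for RNF144B (-2.53, SE 0.246), SLC1A3 (-2.48), TNFSF10, a death receptor ligand (-2.30), ST6GALNAC1 (-2.06) and SHROOM2 (-2.02), each with an adjusted p of at most 2.06e-07. MT1E was detected on 2 of the 3 arrays of both OV2008 groups, and SLC1A3 and SHROOM2 on 1 of the 3 treated arrays of MCAS. DNA replication genes had a lower effect in MCAS in 42 of 49 members (43 lower and 1 higher adjusted over the list alone, median difference -0.92, adjusted p = 1.52e-25). ERK output genes had a higher effect there in 19 of 29 and a lower one in 1 (21 and 2 adjusted over the list alone, median 0.76, adjusted p = 4.66e-09), and cholesterol synthesis genes a lower one in 10 of 20 (11 lower and 1 higher adjusted over the list alone, median -0.53, adjusted p = 0.000227). Mitosis genes (median -0.35), integrin and laminin genes (0.21) and squamous markers (0.22) passed only with the preset correlation, with adjusted p = 0.169, 0.0933 and 0.12 with an estimated correlation. Of the 32 squamous markers, 11 were detected on all 3 DMSO arrays at 6 h in MCAS and 27 in OV2008. Median, mean and test differed in sign for the receptor, p53 and NRF2 lists, which did not pass. In all 2618 genes differed at 6 h, 1258 higher and 1360 lower in MCAS, and the share higher of 48.1% became 37.6% under median scaling and 58.3% under median scaling over detected probes. The count was 1521 under median scaling and 2505 under median scaling over detected probes.

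At 24 h the effect in MCAS was above that in OV2008 for CXCL14 (difference 3.84, SE 0.320, adjusted p = 3.07e-09), NR4A2 (2.56), SERPINE2 (2.06), the cell cycle inhibitor CDKN2B (1.90) and BNIP3 (1.88), which was detected on 1 array of each MCAS group at 24 h. It was below for PLAC8 (-3.75, SE 0.201), ANGPTL4 (-3.16), FADS1 (-2.97), CEACAM5 (-2.80) and DDIT4 (-2.66), each with an adjusted p of at most 1.23e-06. CEACAM5 was detected on 1 of the 3 DMSO arrays of OV2008, and ANGPTL4 and FADS1 on 1 of the 3 treated arrays of MCAS. Mitosis genes fell more in MCAS in 57 of 61 members (59 adjusted over the list alone, median difference -1.05) and DNA replication genes in 44 of 49 (44 adjusted over the list alone, median -1.35), both with an adjusted p = 2.29e-36, and cholesterol synthesis genes in 19 of 20 (19 adjusted over the list alone, median -1.33, adjusted p = 9.64e-19). The endoplasmic reticulum stress list differed by a median of -0.40 (10 of 25 lower, 12 adjusted over the list alone), the ATF4 list by -0.32, the fatty acid list by -0.30 and the inflammatory list by -0.22, each with an adjusted p of at most 0.00403. All 7 of these lists also passed with an estimated correlation. Glycolysis and hypoxia genes (median -0.28), lysosomal genes (0.18), NRF2 targets (-0.24), squamous markers (0.37) and mucinous markers (-0.10) passed only with the preset correlation, with adjusted p = 0.536, 0.163, 0.121, 0.0623 and 0.142 with an estimated correlation. The call of the lysosomal list ended without background correction (adjusted p = 0.0825) and that of the NRF2 list under median scaling (adjusted p = 0.0734). Of the 26 inflammatory genes, 11 were detected on all 3 DMSO arrays at 6 h in OV2008 and 26 in MCAS. Of the 32 squamous markers, 27 were so detected in OV2008 and 11 in MCAS. The differences of these 2 lists may thus partly reflect members near background in 1 line. In all 2911 genes differed at 24 h, 1445 higher and 1466 lower in MCAS, and under median scaling the median difference of all genes was 0.11. The PI3K component, G1 and pro-apoptotic lists, which did not pass, had a median, mean and test of unlike sign.

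In OV2008, 42 of 61 mitosis genes had a lower effect at 24 h than at 6 h and none a higher one (53 adjusted over the list alone, median difference -0.62, adjusted p = 3.88e-29). Ribosome biogenesis genes had a higher effect at 24 h in 10 of 57 (20 adjusted over the list alone, median 0.35, adjusted p = 1.02e-11) and ribosomal protein genes in 5 of 78 (5 adjusted over the list alone, median 0.04, adjusted p = 0.0351). FOXO targets had a lower effect in 11 of 35 (15 lower and 1 higher adjusted over the list alone, median -0.32, adjusted p = 6.77e-06) and squamous markers in 11 of 32 (15 lower and 3 higher adjusted over the list alone, median -0.40, adjusted p = 6.84e-05). Those 5 lists also passed with an estimated correlation. These differences include changes of the DMSO cultures between the times. In those cultures ribosome biogenesis genes fell, and FOXO targets and squamous markers rose, each by a median larger in size than the difference. The lists for glycolysis and hypoxia (median -0.38), DNA replication (-0.30), heat shock (0.28), aminoacyl-tRNA synthetases (0.24), fatty acid synthesis (-0.21), NRF2 (-0.12) and mucinous markers (-0.12) passed only with the preset correlation, with adjusted p = 0.187, 0.0604, 0.128, 0.128, 0.0638, 0.0604 and 0.128 with an estimated correlation. Single genes with the largest differences were EDN2 (2.07), TAGLN (1.97), VPS9D1-AS1 (1.57), VTRNA2-1 (1.504) and PSG5 (1.499), and in the other direction COXFA4L2 (-4.00, SE 0.210, adjusted p = 1.78e-11), AKR1C2 (-1.79), LOX (-1.74), AKR1C3 (-1.68) and CNTN1 (-1.52), each with an adjusted p of at most 0.00298. VTRNA2-1 was detected on 1 of the 3 treated arrays at 6 h and COXFA4L2 on 2 at 24 h, and VPS9D1-AS1 was detected on 2 of the 3 DMSO arrays at 24 h and PSG5 on 1 at each time. In all 901 genes differed, 353 higher and 548 lower at 24 h. Under median scaling 238 did, with a share higher of 52.9% in place of 39.2%, and under median scaling over detected probes 772 did, with 41.6% higher. The count was 595 without OV2008 BEZ235 6 h replicate A. The fatty acid call ended under median scaling (adjusted p = 0.0735). Signs of median, mean and test differed for the ATF4, pro-apoptotic, p53, antigen presentation and endoplasmic reticulum stress lists, which did not pass.

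In MCAS the effect at 24 h lay below that at 6 h for 60 of 61 mitosis genes (60 adjusted over the list alone, median difference -1.42, adjusted p = 2.67e-42) and 33 of 49 DNA replication genes against 1 above (34 and 3 adjusted over the list alone, median -0.68). It also lay below for 12 of 20 cholesterol synthesis genes (13 adjusted over the list alone, median -0.83) and 16 of 29 ERK output genes (19 adjusted over the list alone, median -0.75). Mucinous markers (17 of 29 lower and 2 higher, 18 and 2 adjusted over the list alone, median -0.64), inflammatory genes (15 of 26 lower and 3 higher, 17 and 3 adjusted over the list alone, median -0.66), fatty acid synthesis (median -0.44), endoplasmic reticulum stress (-0.44), NRF2 (-0.41) and integrin and laminin genes (-0.30) were lower too, and ribosomal protein genes were higher (0.17). Each of these 11 lists had an adjusted p of at most 0.00359 and also passed with an estimated correlation. The call of the ribosomal protein list ended under median scaling over detected probes (adjusted p = 0.0630). Glycolysis and hypoxia genes (-0.54), ribosome biogenesis genes (0.28) and heat shock genes (0.39) passed only with the preset correlation, with adjusted p = 0.144, 0.180 and 0.0662 with an estimated correlation. PAEP (2.11, SE 0.126, adjusted p = 2.83e-11), SYT13 (2.04), SNHG1 (1.81), the chemokine CCL22 (1.75) and BTN3A3 (1.73) had the largest differences upward, and DMBT1 (-3.61, SE 0.192), the metallothionein MT1X (-3.56), RARRES1 (-3.28), ALDH3A1 (-3.11) and the prostaglandin synthase PTGS2 (-2.94) downward, each with an adjusted p of at most 3.79e-06. CCL22 was detected on 2 of the 3 treated arrays at 6 h and DMBT1 on 1 at 24 h. These differences include changes of the DMSO cultures between the times, in which MT1X rose by 3.41. In all 3854 genes differed, 1946 higher and 1908 lower at 24 h. Under median scaling the share higher of 50.5% was 74.1% and the median difference of all genes 0.19, and under median scaling over detected probes they were 40.8% and -0.09.

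Across genes, which are not replicates, the effects in OV2008 and MCAS correlated at r = 0.434 at 6 h and 0.455 at 24 h, in comparisons that share no arrays. At 6 h 802 genes were higher in both lines (350 expected from the counts) and 819 lower in both (373), and 201 were called in opposite directions (723). At 24 h the numbers were 909 (389), 1004 (422) and 220 (818). Both lines shared the rise of IRS2 and the falls of HMGCS1, FASN and PFKFB4. Between 6 h and 24 h the effects, which share no arrays either, correlated at 0.606 in OV2008 and 0.483 in MCAS.

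**Figure D4:**
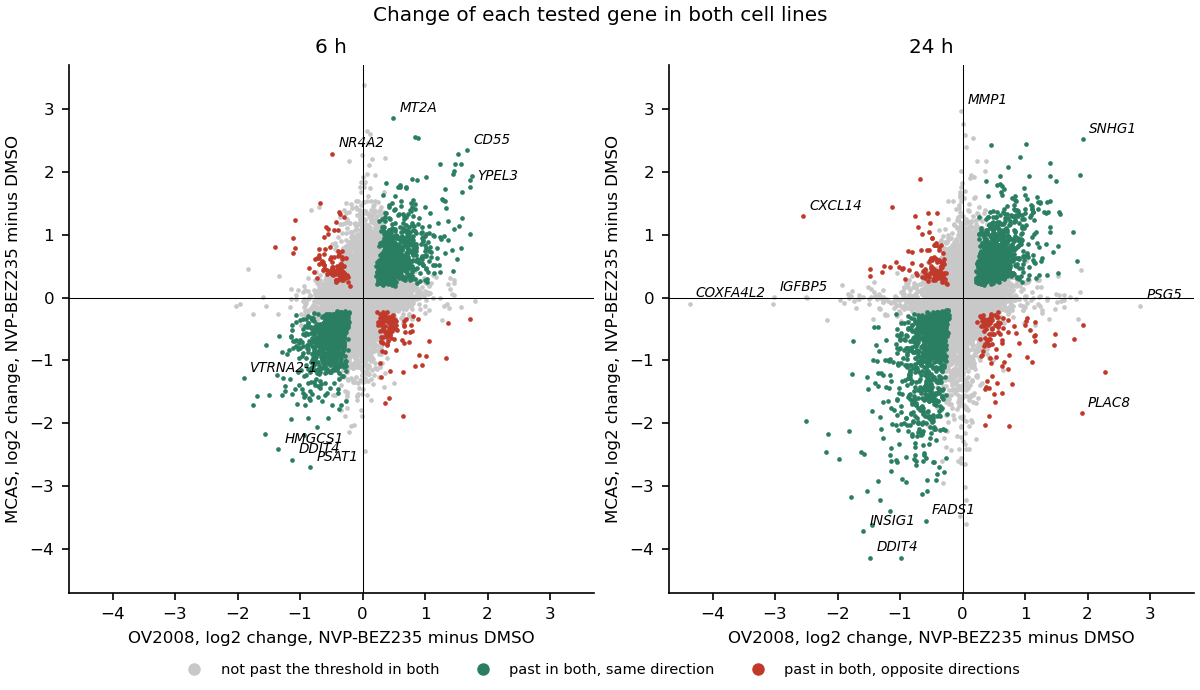
Log2 change with BEZ235 of each tested gene in OV2008 (horizontal axis) and MCAS (vertical axis) at 6 h and 24 h; points are genes, coloured by whether the gene was called in both lines and in which directions. At 6 h 802 and 819 genes were called higher and lower in both and 201 in opposite directions, and at 24 h 909, 1004 and 220.

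Without the drug, the lines differed strongly. Under DMSO, averaged over both times, MCAS had higher levels of S100A4, a calcium-binding protein (7.91, SE 0.0867, adjusted p = 3.10e-28, 241-fold), the chemokine CXCL8 (6.70), the mucin MUC1 (6.61), ACSL5 (6.22) and LCN2 (6.19). OV2008 had higher levels of the non-coding RNA SNAR-A1 (difference -8.62, SE 0.0743, 394-fold), OLFML2A (-7.24), GJB6 (-6.15), ZBTB7C (-6.08) and the interleukin receptor IL20RB (-5.92). ACSL5 was detected on 5 of the 6 DMSO arrays of OV2008, and SNAR-A1, OLFML2A, GJB6, ZBTB7C and IL20RB on 5, 4, 3, 3 and 2 of the 6 of MCAS. Mucinous markers were higher in MCAS in 26 of 29 and lower in 3 (26 and 3 adjusted over the list alone, median 1.90, adjusted p = 5.63e-10) and squamous markers lower in 27 of 32 and higher in 4 (27 and 4 adjusted over the list alone, median -2.33, adjusted p = 2.78e-08). That both lines are ovarian was taken from the labels and was not checked, and the squamous markers of OV2008 leave it in doubt for that line. Inflammatory genes (23 of 26 higher and 2 lower, 23 and 3 adjusted over the list alone, median 3.06) and endoplasmic reticulum stress genes (21 of 25 higher and 3 lower, 21 and 3 adjusted over the list alone, median 0.98) were higher in MCAS. So were antigen presentation genes (median 0.79) and cholesterol synthesis genes (0.85), each of the 4 with an adjusted p of at most 0.00793. These 6 lists also passed with an estimated correlation. Interferon-stimulated genes (0.52), ERK output genes (1.51), ribosome biogenesis (0.24), DNA replication (-0.37) and mitosis genes (-0.50) passed only with the preset correlation, with adjusted p = 0.0945, 0.104, 0.458, 0.455 and 0.271 with an estimated correlation. The DNA replication and ribosome biogenesis calls ended under median scaling (adjusted p = 0.0725 and 0.0543). Signs of median, mean and test differed for the receptor, PI3K component, pro-survival, pro-apoptotic, integrin, heat shock and mesenchymal lists, none of which passed. In all 8736 genes (78.9%) differed, 4128 higher and 4608 lower in MCAS.

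The control cultures changed between 6 h and 24 h as well. In DMSO-treated MCAS, MT1X (3.41), NDRG1 (3.01), ANGPTL4 (2.78), the glucose transporter SLC2A3 (2.19) and DEPP1 (1.94) had the largest rises. OASL (-1.65), ALOX5AP (-1.29), NDUFAF4 (-1.28), TIPIN (-1.24) and GPAT3 (-1.24) had the largest falls, and all of these genes had an adjusted p of at most 6.68e-05. OASL and GPAT3 were detected on 2 of the 3 arrays at 24 h. Of 37 glycolysis and hypoxia genes, 28 rose (29 adjusted over the list alone, median 0.66, adjusted p = 3.20e-13, and adjusted p = 0.0980 with an estimated correlation). DNA replication genes fell in 39 of 49 (41 adjusted over the list alone, median -0.56, adjusted p = 4.37e-20) and ribosome biogenesis genes in 34 of 57 (37 adjusted over the list alone, median -0.45, adjusted p = 4.05e-15). Mucinous markers rose in 14 of 29 (15 adjusted over the list alone, median 0.31, adjusted p = 4.47e-05). These 3 lists also passed with an estimated correlation. Lists for FOXO targets (0.32), receptors (0.33), integrins (0.23), aminoacyl-tRNA synthetases (-0.31), ATF4 targets (-0.11) and NRF2 targets (-0.20) passed only with the preset correlation, with adjusted p = 0.0980, 0.106, 0.0980, 0.0980, 0.172 and 0.106 with an estimated correlation. The ATF4 call ended under median scaling (adjusted p = 0.0567). In all 3185 genes changed, 1662 higher and 1523 lower. The share higher of 52.2% became 34.2% under median scaling, where 2069 genes passed, and 60.1% under median scaling over detected probes, where 3303 passed. The count was 1996 without MCAS DMSO 24 h replicate A. Signs of median, mean and test differed for the G1, pro-apoptotic, antigen presentation, squamous and mesenchymal lists, which did not pass.

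In DMSO-treated OV2008, NREP (1.82), NDRG1 (1.80), VLDLR (1.69), CXCL14 (1.69) and KRT16P2 (1.66) rose the most. The immediate early gene FOSB (-1.93), MTHFD1L (-1.71), VPS9D1-AS1 (-1.44), IL1RAP (-1.44) and RRP12, a ribosome assembly gene (-1.39), fell the most, each with an adjusted p of at most 0.000188. NREP was detected on 2 of the 3 arrays at 6 h and VPS9D1-AS1 on 2 of the 3 at 24 h. Ribosome biogenesis genes fell in 37 of 57 (46 adjusted over the list alone, median -0.49, adjusted p = 1.76e-20), aminoacyl-tRNA synthetases in 8 of 16 (8 adjusted over the list alone, median -0.25), oxidative phosphorylation genes in 11 of 48 (11 adjusted over the list alone, median -0.18). Falls also prevailed among cholesterol synthesis genes, in 11 of 20 against 2 that rose (11 and 3 adjusted over the list alone, median -0.34) and endoplasmic reticulum stress genes in 11 of 25 against 1 (11 and 2 adjusted over the list alone, median -0.25). FOXO targets rose in 18 of 35 and fell in 2 (18 and 2 adjusted over the list alone, median 0.37) and squamous markers rose in 16 of 32 and fell in 1 (16 and 2 adjusted over the list alone, median 0.47). Each of these 7 lists had an adjusted p of at most 0.000479 and also passed with an estimated correlation. The lists for glycolysis and hypoxia (0.22), lysosome (0.11), interferon (0.08), inflammation (-0.06), ERK output (-0.15) and DNA replication (-0.21) passed only with the preset correlation, with adjusted p = 0.257, 0.0927, 0.186, 0.0794, 0.101 and 0.114 with an estimated correlation. The inflammatory call ended without background correction (adjusted p = 0.0506). In all 2568 genes changed, 1376 higher and 1192 lower, against 1446 under median scaling, 2538 under median scaling over detected probes and 1612 without OV2008 DMSO 6 h replicate B. Signs of median, mean and test differed for the antigen presentation list, which did not pass.

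In the panel of genes of growth signalling, survival and metabolism, HMGCS1, SCD, HK2 and DDIT4 fell in all 4 comparisons (again in the order OV2008 at 6 h, OV2008 at 24 h, MCAS at 6 h and MCAS at 24 h). The changes were -1.35, -1.07, -2.42 and -2.59 for HMGCS1, -0.47, -1.62, -0.64 and -2.46 for SCD, -1.18, -1.16, -0.83 and -0.97 for HK2, and -1.13, -1.48, -2.58 and -4.14 for DDIT4. The glucose transporter SLC2A1 fell in 3 of them (-0.44, -1.37 and -1.01) but not in MCAS at 6 h (0.18, adjusted p = 0.147), where it was called at 0.28 without MCAS BEZ235 6 h replicate A. ERBB3 was higher in all 4 (0.69, 0.59, 0.71 and 0.68), though its call in OV2008 at 24 h ended with the mean of its probes (0.21). IRS1 was at 0.31 (adjusted p = 0.0740) and -0.18 (adjusted p = 0.296) in MCAS, and its effect there was below that in OV2008 by a difference of -1.09 at 6 h (adjusted p = 0.000287) and -1.66 at 24 h. IRS1 was detected on no DMSO array of OV2008 at 6 h and on 1 of the 3 at 24 h. The transcription factor MYC rose in MCAS (1.40 and 0.75), and its rise in OV2008 (0.50 and 0.36) did not pass under median scaling. FOXO1 rose in MCAS (1.07 and 0.68) and FOXO3 in MCAS at 6 h (0.82), while in OV2008 at 6 h their values (0.43 and 0.44) did not pass under median scaling. PIK3IP1 rose in OV2008 at both times (1.57 and 0.61) and in MCAS at 6 h (0.78), and was at 0.26 in MCAS at 24 h (adjusted p = 0.0773). The cell cycle inhibitor CDKN1B rose in MCAS at 24 h (0.85), and in OV2008 it was at 0.41 and 0.50, values that did not pass under median scaling. The survival gene BCL2 rose in OV2008 at 6 h (0.69, adjusted p = 0.00142). At 24 h it was at 0.45 there (adjusted p = 0.0255), which did not pass under median scaling (adjusted p = 0.0743) or without OV2008 DMSO 24 h replicate A (0.143), BEZ235 24 h replicate A (0.0653) or BEZ235 24 h replicate B (0.0658). In MCAS BCL2 was at -0.18 at 6 h (adjusted p = 0.345, detected on 2 of the 3 treated arrays). At 24 h in MCAS BCL2 was detected on 1 DMSO array and no treated array and was not called (adjusted p = 0.0678), but it was called as lower without MCAS DMSO 24 h replicate C (adjusted p = 0.00986) and without MCAS BEZ235 24 h replicate C (0.00802). None of the values of BCL2L1 (0.45, 0.26, 0.15 and 0.25), MCL1 (0.36, 0.25, -0.21 and 0.08), BCL2L11 (0.12, -0.38, 0.30 and -0.13) and CCND1 (-0.45, 0.13, 0.25 and 0.00) passed under every setting tried, and BCL2L11 was detected on 2 of the 3 treated arrays of OV2008 at 6 h and, in MCAS, on 2 treated and 1 DMSO array at 6 h and 2 of each at 24 h. ERBB2 rose in MCAS at 6 h (0.79), EGFR in OV2008 at 6 h (0.79) and in MCAS (0.83 and 0.67), and MTOR fell in OV2008 (-0.45 and -0.45). ASNS, an enzyme of asparagine synthesis, fell in MCAS at 6 h (-0.62), and CCNG2 rose in OV2008 at 6 h (0.65). The values of these 5 genes in the other comparisons did not pass under every setting tried. IGF1R and SESN1 were detected on no array of MCAS.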

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

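The tests of the small nucleolar RNA host genes outside MCAS at 6 h, of dim probes in OV2008 and of a rise in DMSO cultures alone were chosen only after the result was seen. What set the following results apart was a limma test of the difference between the effects of BEZ235 in the 2 cell lines or at the 2 times. At 6 h 2618 genes differed between the lines. NR4A2 (2.78), FAM43A (2.48), MT2A (2.37), MT1E (2.37) and TMEM158 (2.32) had the higher effect in MCAS, and RNF144B (-2.53), SLC1A3 (-2.48), TNFSF10 (-2.30), ST6GALNAC1 (-2.06) and SHROOM2 (-2.02) the lower one. IRS1 (-1.09, with OV2008 DMSO arrays below detection), HMGCS1 (-1.07) and DDIT4 (-1.45) differed as well, as did the medians of the cholesterol synthesis (-0.53), DNA replication (-0.92) and ERK output lists (0.76).

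At 24 h 2911 genes differed, led by effects higher in MCAS for CXCL14 (3.84), NR4A2 (2.56), SERPINE2 (2.06), CDKN2B (1.90) and BNIP3 (1.88, dim there) and lower for PLAC8 (-3.75), ANGPTL4 (-3.16), FADS1 (-2.97), CEACAM5 (-2.80) and DDIT4 (-2.66). IRS1 (-1.66) and HMGCS1 (-1.52) differed too. Lists with a lower effect in MCAS were DNA replication (median -1.35), cholesterol synthesis (-1.33), mitosis (-1.05), endoplasmic reticulum stress (-0.40), ATF4 targets (-0.32), fatty acid synthesis (-0.30) and inflammatory genes (-0.22). Only 11 of the 26 inflammatory genes were detected on all 3 DMSO arrays of OV2008 at 6 h.

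Between 24 h and 6 h the effect in OV2008 differed for 901 genes, among them EDN2 (2.07), TAGLN (1.97), VPS9D1-AS1 (1.57), VTRNA2-1 (1.504), PSG5 (1.499), COXFA4L2 (-4.00), AKR1C2 (-1.79), LOX (-1.74), AKR1C3 (-1.68), CNTN1 (-1.52) and SCD (-1.16), and for the lists of mitosis (-0.62), squamous (-0.40), FOXO (-0.32), ribosome biogenesis (0.35) and ribosomal protein genes (0.042). In MCAS it differed for 3854 genes, among them PAEP (2.11), SYT13 (2.04), SNHG1 (1.81), CCL22 (1.75), BTN3A3 (1.73), DMBT1 (-3.61), MT1X (-3.56), RARRES1 (-3.28), ALDH3A1 (-3.11), PTGS2 (-2.94), SCD (-1.81), DDIT4 (-1.56) and SLC2A1 (-1.19). The lists that differed in MCAS were mitosis (-1.42), cholesterol synthesis (-0.83), ERK output (-0.75), DNA replication (-0.68), inflammatory (-0.66), mucinous (-0.64), fatty acid synthesis (-0.44), endoplasmic reticulum stress (-0.44), NRF2 (-0.41), integrin and laminin (-0.30) and ribosomal protein genes (0.17). In both lines these differences include changes of the DMSO cultures between the times.

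Probes without a single gene symbol, which no comparison used, changed too. Of 3631 such probes, 611, 969, 1126 and 1400 passed in OV2008 at 6 h, OV2008 at 24 h, MCAS at 6 h and MCAS at 24 h, and 21, 80, 127 and 190 changed at least 2-fold.

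Host genes of small nucleolar RNAs, noticed through SNHG1, SNHG7 and TAF1D, were tested again on the other 14. Outside MCAS at 6 h their rise was above all 10000 random lists of like brightness (percentile 100), exceeded that of other long non-coding RNAs by at least 0.39 (SE 0.0559) and stayed at 0.27 (SE 0.102) or more under every scaling, which argues against probe brightness, a shift of all long non-coding RNAs and scaling as the cause there. In MCAS at 6 h the rise exceeded that of other long non-coding RNAs by 0.13 (SE 0.0559), but lay at percentile 94.8, so brightness stays open there. Median scaling turned the mean in MCAS at 6 h from 0.17 (SE 0.0557) to -0.067 (SE 0.102), while it was 0.24 (SE 0.0654) under median scaling over detected probes, 0.18 without background correction and 0.18 with offset 50, so its size and sign depend on the scaling chosen. A response of these transcripts to BEZ235 outside MCAS at 6 h may be biological and is a hypothesis found on the same data.

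The fall of DNA replication genes at 6 h was deeper in MCAS by a mean of -0.89 (SE 0.06). The smallest difference under any scaling was -0.76 (no background correction) and with any single array left out -0.87 (without MCAS BEZ235 6 h replicate A), which argues against scaling or a single array as the cause. Dim probes in OV2008 are argued against by a baseline that was lower in MCAS (-0.33). A difference between the cell lines may be its source, as a hypothesis, and a difference in timing alone was not tested.

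Glycolysis and hypoxia genes fell at 24 h while the same genes rose in DMSO cultures between 6 h and 24 h (mean 0.69 in MCAS, 0.36 in OV2008). Treated cultures at 24 h lay below DMSO cultures at 6 h by a mean of -0.34 in MCAS and -0.39 in OV2008 (SE 0.0954 for both), which argues against the rise in DMSO cultures as the whole cause. Under every scaling the mean effect was -0.95 or lower in MCAS and -0.67 or lower in OV2008, which argues against scaling. An effect of BEZ235 itself may be the source, as a hypothesis, and the culture conditions that raised the genes in DMSO were not tested.

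Other splits of the same arrays were counted on the arrays compared alone. Of the 10 splits of 3 against 3 arrays only the real 1 gave as many genes or lists, and the smallest share this design allows is 0.1. The real and highest other counts of genes were 3585 and 0 in OV2008 at 6 h, 3239 and 0 at 24 h, 4123 and 0 in MCAS at 6 h, 4785 and 0 at 24 h, and for DMSO over time 1914 and 0 in OV2008 and 2924 and 0 in MCAS. For lists they were 12 and 10, 16 and 9, 15 and 11, and 16 and 11 in the order of the 4 effects. For the differences, splits that relabel treatment within each line or time also remove the shared effect, so they were not used to exclude chance. Of 100 of these, 2 gave as many genes between the lines at 6 h (2445 real, 2466 highest other) and 4 at 24 h (2713 and 5632, the latter with the labels of 1 line reversed, so that it adds the effects up). Between times 2 gave as many in OV2008 (1061 and 1064) and 2 in MCAS (3251 and 5593, again with the labels of 1 time reversed). In a test added later, each gene was centred within line or time and the arrays of each treatment were dealt to the 2 lines or times, which keeps the shared effect. Of 100 such splits only the real 1 gave as many genes in each of the 4 differences. The highest other counts were 1 and 0 between the lines at 6 h and 24 h, and 1 and 1363 between times in OV2008 and MCAS. A random deal of these arrays thus seldom gave such counts. Chance differences between cultures are not excluded. For the lines under DMSO only the real of 100 splits gave as many (8686, highest other 4567).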

How the results depend on the processing

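Median scaling over detected probes and the replicate block were not planned. Of 59 called lists in the 4 effects, 33 kept their call under every alternative and 51 under all but an estimated correlation. Over all 11 contrasts 515 of 603 named-gene calls were kept, genes absent from a setting included. The counts of genes in the 4 effects stayed within 1.5 times of those reported (2457 to 4098 in OV2008 at 6 h). Median scaling gave 1521 genes for the line difference at 6 h (2618), 238 for the time difference in OV2008 (901), 1446 for DMSO over time in OV2008 (2568) and 2069 in MCAS (3185), and array weights 1420 for the time difference in OV2008. With 1 array left out these counts ranged from 595 to 914 for the time difference in OV2008, from 1612 to 2380 for DMSO over time in OV2008 and from 1996 to 3108 in MCAS. An estimated correlation left 5 of 14 lists in OV2008 at 6 h and 10 of 16 in MCAS at 24 h, and fry passed 23 in MCAS at 6 h and 29 at 24 h. The correlation between the lines at 6 h (0.434) was 0.469 without background correction, 0.462 with offset 50, 0.462 with either median scaling, 0.4005 in the authors' value table, 0.405 without a filter and 0.525 for genes detected on all arrays. At 24 h (0.455) these were 0.495, 0.485, 0.419 in the value table and 0.558 on all arrays, and the other alternatives moved it by less than its spread. CDKN1B in MCAS DMSO cultures over time was -0.28 with the mean of its probes (adjusted p = 0.0317) against 0.00. The cause was not tested for any of these. The lowest array weights were 0.344 (MCAS BEZ235 6 h replicate A) and 0.422 (OV2008 DMSO 24 h replicate A). With numbers as a replicate block on the value table, 2901, 3251, 4837 and 4959 genes passed in the 4 effects and the correlations were 0.4005 and 0.419, but the numbers do not pair the samples: r between same-numbered samples lay between -0.0594 and 0.121 over 12 pairs, 2 above 0.1, and 5 matched their own number best. A chip block was not run, since no column names a chip. Signal near background limits dim genes.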

Other observations

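The gene families described here were chosen after their values were seen. Host genes of small nucleolar RNAs, the RNAs that guide modification of ribosomal RNA, rose in 11 of 17 members in OV2008 at 6 h (1 fell), 15 at 24 h and 15 in MCAS at 24 h (medians 0.62, 0.86 and 0.82, adjusted p = 0.0024, 0.000272 and 0.00156 with an estimated correlation). In MCAS at 6 h 8 rose and 2 fell (median 0.29, adjusted p = 0.117 with an estimated correlation), and the effect in MCAS was higher at 24 h than at 6 h in 13 of 17 (median difference 0.88, adjusted p = 0.00596 with an estimated correlation). In DMSO-treated MCAS 8 of the 17 fell between the times and none rose (median -0.28, adjusted p = 0.00268, and adjusted p = 0.0972 with an estimated correlation), so part of that difference may lie in the controls. Pregnancy-specific glycoprotein genes, whose near-identical copies the probes may not tell apart, rose in 5 of 5 members in OV2008 at 24 h (median 1.85). PSG4, PSG5, PSG6 and PSG9 passed the filter only through treated OV2008 arrays, so neither this count nor a list test decides. All 5 were detected on all 3 treated arrays there, but PSG3 and PSG5 on 1 DMSO array, PSG4 on 1 by another probe only, and PSG6 and PSG9 on none, so the median is uncertain. In MCAS at 24 h PSG3 was detected on all 3 DMSO and no treated arrays and was at least 1.75-fold lower (adjusted p = 9.63e-07). PSG5, PSG6 and PSG9 were detected on no array of MCAS and PSG4 on 1, so their response there is open.

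Metallothioneins, which bind metal ions, rose in 5 of 5 members in MCAS at 6 h (median 1.29, adjusted p = 0.0213 with an estimated correlation), where the effect was higher than in OV2008 in 5 of 5 (median difference 1.65, adjusted p = 0.0193 with an estimated correlation). In MCAS MT1G was detected only on the arrays treated for 6 h. By 24 h MT1E and MT2A were still higher (1.07 and 1.07) while MT1X, which rose by 3.41 between the times in DMSO cultures, was at -2.39. The effect was lower than at 6 h in 5 of 5 (median difference -1.47, adjusted p = 0.0122 with an estimated correlation). Clustered histone genes rose in 15 of 28 in OV2008 at 6 h (median 0.41), in 18 in MCAS at 6 h against 1 that fell (0.42) and in 18 at 24 h against 3 (0.87), with adjusted p = 0.0929, 0.109 and 0.101 with an estimated correlation. In OV2008 at 24 h 7 rose and 1 fell (median 0.15, adjusted p = 0.0532). Of the 28, H3C4, H4C5, H2AC21 and H2BC18 were detected on no array of OV2008, and H3C4 and H4C5 on none of MCAS at 6 h.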
